A study of Rattus norvegicus with 8 samples.

How the data were processed

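Lungs were perfused, minced and dissociated, the cells of each animal barcoded (MULTI-seq) and pooled, and 2 aliquots of each pool run on separate 10x 3' channels, per the labels. The deposited files hold raw UMI counts per gene and cell barcode from Cell Ranger against Rnor_6.0, per the submitters' processing notes, with versions not given in the sources used here. The 4 barcode libraries were not analysed here. Animals, states and cell types come from the authors' deposited cell table, whose barcodes number 20, while the deposited barcode list names 10, so the animals of the other barcodes rest on the table alone. The authors also deposited the percent of mitochondrial counts per cell (at most 29.99%) and 13 of 21 columns not used here. Of 73110 barcodes 47633 are annotated (58.7%, 56.6%, 75% and 71.3% in libraries A1, B1, A2 and B2), with at least 500 UMIs and 0 marked as doublets, and UMI sums equalled the authors' in 90.4% of cells (largest difference 20). The matrix has 25400 genes, 309 rows sharing a symbol with another, tested by their own ID.

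Counts were summed per animal over blood endothelial, arterial endothelial, smooth muscle and pericyte (mural), fibroblast, and macrophage and monocyte cells, with 11763, 2358, 1199, 1517 and 13016 cells, leaving out animals with under 20 cells. The replicate is the animal. edgeR 4.0.16 (R 4.3.3, filterByExpr, TMM, quasi-likelihood, prior count 2) fitted the 5 states, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. Numbers of cells per type were tested by edgeR in 43 types of at least 50 cells. The 25 gene lists were tested with camera (limma 3.58.1, correlation 0.01) where at least 3 members were measured. Where a state held 3 or fewer pooled counts of a gene, ratios of pooled CPM with 95% intervals or bounds replaced fitted folds, and these cover counting error only. Lists, tests and the rule for naming genes were fixed before the data were examined. The rule took, per compartment, up to 12 largest rises and 12 largest falls among genes past the any-week test, with a mean of at least 50 CPM in a state and, in a week that passed, every animal on 1 side of every healthy animal, plus list members with the smallest adjusted p and 11 genes named in advance. The text prints part of these. Summaries and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

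Alternatives were DESeq2 1.42.0, its size factors, no count filter, a minimum of 50 cells, cells thinned to 1000 UMIs, 2 states per fit, each animal left out, experiment as a block, an estimated correlation and fry for lists, and TMM, lineage denominators, limma and a permutation test for shares. Fits of each experiment alone and the block for lists were added after seeing the data. Experiment pairs the replicates per the cell table. Deviations from state means correlated at a mean r of 0.457, 0.228, 0.218, 0.266 and 0.488 within an experiment and at minus these values across, and the first principal component (49%, 27.4%, 26.5%, 32.4% and 52.1%) separated the experiments in each. A check for duplicated counts found none (smallest chi-square per gene 1.5) but cannot exclude 1 animal under 2 barcodes, whose cells differ. On data simulated for week 1 against healthy, with 200 genes changed of 9096, 6533, 4704, 3859 and 9823, the fit recovered 77%, 52%, 21%, 29% and 87% of 2-fold and 99%, 94%, 81%, 84% and 98% of 4-fold changes, with 5.38%, 2.01%, 1.92%, 4.24% and 2.12% false calls. Simulated 4-fold share changes were recovered in 76.5%, with 3.16% false.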

Results

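Lungs of healthy rats and of rats with induced pulmonary arterial hypertension (PAH, high pressure in the lung arteries) at weeks 1, 3, 5 and 8 were dissociated and profiled by droplet single-cell mRNA sequencing. The series asks which disease-specific vascular populations accompany obliterative remodelling of the arteries as the disease develops. Each of the 5 states held 4 animals, replicates 1 and 2 from experiment 1 (libraries A1 and B1) and replicates 3 and 4 from experiment 3 (libraries A2 and B2). The libraries held 59461063, 75730590, 81657522 and 89889164 UMIs (unique molecular identifiers, 1 per captured mRNA). The authors annotated 47633 cells of 44 types, 945 to 4002 cells and 3459798 to 23223349 UMIs per animal, with a median of 2690 per cell. Per animal, UMI sums were 487689 to 2951134 in blood endothelial and 107798 to 1350664 in arterial cells. Depth goes with arterial state, with healthy sums at most 155359 and all others at least 210175. Mural cells, fibroblasts and macrophages and monocytes had 58275 to 477948, 79982 to 331595 and 1625558 to 12298795. Fold changes below are log2 ± SE, levels are mean CPM (counts scaled to the same total) ± SD, and n = 4 animals per state except where given. Counts after a list name are the members that rose and fell of those measured, and over the list means with p adjusted over its members only. With the block means with experiment as a covariate. Arterial cells are also part of the blood endothelial compartment.

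At week 1, 4 of the 7 macrophage and monocyte types rose as shares of lung cells. Changes run from the healthy share. Int. Mac cells rose from 1.26% ± 0.471 to 7.83% ± 1.55 (log2 2.62 ± 0.34, edgeR adjusted p = 8.89e-06), with all 4 animals above every healthy one. Trans. Mono cells rose from 1.43% ± 0.29 to 4.15% ± 1.38 (log2 1.53 ± 0.30, edgeR adjusted p = 0.00105), and Alv. Mac cells from 3.52% ± 0.595 to 8.56% ± 1.26 (log2 1.28 ± 0.39, edgeR adjusted p = 0.0361). Pro. Alv. Mac cells rose from 0.33% ± 0.163 to 0.912% ± 0.178 (log2 1.48 ± 0.48, edgeR adjusted p = 0.048), while the SMCs/Myofibroblast type fell from 1.76% ± 0.697 to 0.337% ± 0.247 (log2 -2.29 ± 0.69, edgeR adjusted p = 0.0361). As shares of their own lineage the last 3 did not pass (edgeR adjusted p = 0.0852, 0.0828 and 0.156). At week 3 Int. Mac cells stood at 2.74% ± 0.913 (log2 1.10 ± 0.33, edgeR adjusted p = 0.0368). Acta2+ pericytes, named for smooth muscle actin, rose from 0.346% ± 0.065 to 1.69% ± 0.375 (log2 2.29 ± 0.41, edgeR adjusted p = 0.000655). Their share was 1.76% ± 0.324 (log2 2.35 ± 0.41, edgeR adjusted p = 0.000466) at week 5 and 1.68% ± 0.973 (log2 2.26 ± 0.41, edgeR adjusted p = 0.000916) at week 8. Lymphatic endothelial cells rose from 0.69% ± 0.17 to 2.52% ± 1.4 (log2 1.87 ± 0.45, edgeR adjusted p = 0.0108) at week 3, and were at 2.09% ± 0.621 (log2 1.60 ± 0.45, edgeR adjusted p = 0.0415) and 1.96% ± 0.746 (log2 1.50 ± 0.46, edgeR adjusted p = 0.0497) at weeks 5 and 8. The arterial type named Act. Arterial rose from 1.41% ± 0.377 to 3.18% ± 0.921 (log2 1.18 ± 0.35, edgeR adjusted p = 0.0368) at week 3, a call lost within the endothelial lineage (adjusted p = 0.325). Brush cells fell from 1.3% ± 1.36 to 0.277% ± 0.172 (log2 -2.20 ± 0.66, edgeR adjusted p = 0.0445) at week 5 and to 0.268% ± 0.134 (log2 -2.36 ± 0.70, edgeR adjusted p = 0.0497) at week 8, where as a share of epithelial cells the edgeR adjusted p was 0.203 and 0.249. Healthy replicate 3 held 3.32% Brush cells and the other healthy animals 0.43% to 0.937%. Without it the adjusted p was 0.327 and 0.3, and leaving out 10 and 14 of the other 19 animals, 1 at a time, also ended these calls (up to 0.141 and 0.183). TMM scaling of the cell numbers ended the lymphatic calls at weeks 5 and 8 (adjusted p = 0.106 and 0.107) and the week 1 calls of Alv. Mac, Pro. Alv. Mac and SMCs/Myofibroblast (0.0813, 0.0969 and 0.0576). Leaving out 1 animal could end these 5 too (0.184 and 0.198 without healthy replicate 3, and up to 0.092, 0.154 and 0.112), and Act. Arterial and Int. Mac at week 3 (up to 0.133 and 0.105).

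Of 43 types tested, 5, 4, 3 and 3 passed at weeks 1, 3, 5 and 8, against 14, 17, 12 and 8 with the block. Experiment 1 alone gave 8, 12, 7 and 6 types and experiment 3 alone 3, 1, 10 and 3. Types that passed only with the block had Inflammatory ECs and Neutrophil higher and AT2-a, Arterial, B cell, Brush cell, Cd16+ Mono, Col13a1+ Fibroblast and Pro. NK cell lower at week 1 (edgeR adjusted p = 0.0016 to 0.0496). At week 3 they were Alv. Mac, Arterial, Inflammatory ECs and Venous higher and AT2-a, Act. NK cell, B cell, Brush cell, Cd14+ Mono, Cd4+ T cell, DC-3, SMCs/Myofibroblast and cDC lower (adjusted p = 1.63e-05 to 0.0421). Week 5 added Act. Arterial, Alv. Mac, Arterial, Col13a1+ Fibroblast, Inflammatory ECs and Pdzd2+ Pericyte higher and AT2-a, Cd4+ T cell and Cd8+ T cell lower (adjusted p = 0.00239 to 0.0438), and week 8 Alv. Mac, Arterial, NKT cell and Pdzd2+ Pericyte higher and AT2-a lower (adjusted p = 0.00409 to 0.018). The exact two-sided permutation test of each share, with 70 labellings, cannot go below p = 0.0286 and called 0 types after adjustment. Summed over the weeks, 15 calls became 7 without healthy replicate 3, 8 without healthy replicate 4, 9 without week 1 replicate 1, 9 without week 1 replicate 3. Compared directly, week 8 differed from week 1 in 7 types, 13 with the block. Acta2+ pericytes (log2 fold change 1.70), Arterial (1.59), Col13a1+ fibroblasts (2.04) and Pdzd2+ pericytes (1.82) were higher at week 8. Int. Mac (-2.10), Trans. Mono (-0.94) and aCap cells (-1.44) were lower, with edgeR adjusted p = 0.000173 to 0.0434 over the 7. Within their lineage Acta2+ and Pdzd2+ pericytes, Col13a1+ fibroblasts, Trans. Mono and aCap cells did not pass (adjusted p = 0.203, 0.196, 0.112, 0.0799 and 0.0799), nor Arterial with TMM scaling (0.0589). With 1 animal left out these but Acta2+ pericytes reached 0.0815 to 0.172.

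**Figure D1:**
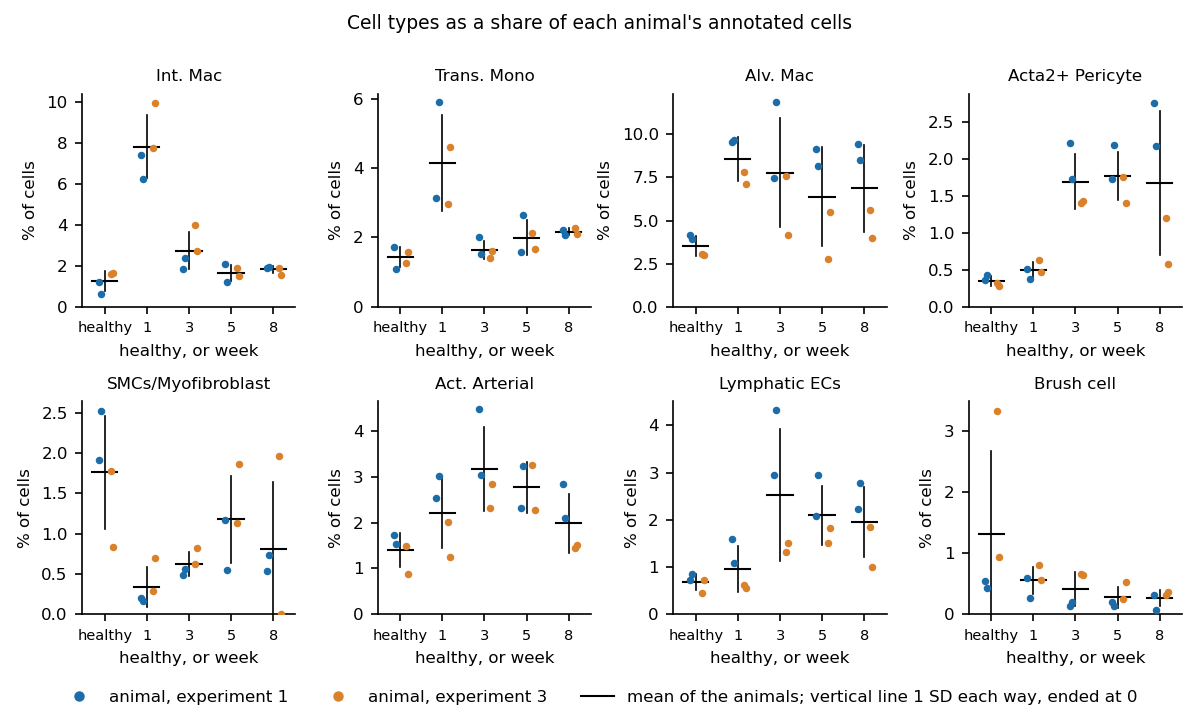
Share of each animal's annotated cells (%, y axis) held by 8 cell types in the 5 states (x axis). Points are animals coloured by experiment, with mean and 1 SD, ended at 0; Int. Mac and Trans. Mono stand highest at week 1, and Acta2+ Pericyte stands above its healthy level at weeks 3, 5 and 8.

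Blood endothelial cells at week 1 expressed far more of the xenobiotic-metabolising enzymes Cyp1a1, Cyp1b1 and Nqo1 and of mitotic genes. Cyp1a1 went from 358 ± 158 to 5144 ± 608 CPM (log2 3.85 ± 0.38, edgeR adjusted p = 1.41e-05), Cyp1b1 from 95 ± 72.6 to 1454 ± 180 (3.95 ± 0.63) and Nqo1 from 70.2 ± 44.2 to 986 ± 501 (3.82 ± 0.67). The mitotic genes Ube2c, Prc1 and Pttg1 rose by 4.05, 3.77 and 3.75. Igfbp3, which binds insulin-like growth factors, fell from 66.2 ± 63.1 to 1.23 ± 0.974 CPM (log2 -5.56 ± 0.94, edgeR adjusted p = 0.00114). The Notch ligand Dll4 changed by -2.72 ± 0.25, the receptor tyrosine kinase Kit by -1.90 ± 0.25, the prostaglandin-degrading enzyme Hpgd by -2.70 ± 0.65 and Bmpr2, the BMP receptor whose mutations cause heritable PAH, by -0.93 ± 0.14 (edgeR adjusted p = 0.00047). In the cell cycle list, higher by camera (adjusted p = 4.74e-20, 0.0205 with estimated correlation), 10 rose and 0 fell of 16 (13 and 0 over the list). Members included Cdk1 2.96 ± 0.37 and Tpx2 3.98 ± 0.58. Of the hypoxia response genes, higher by camera (adjusted p = 1.92e-07, 0.0205 with estimated correlation), 6 rose and 1 fell of 13 (7 and 1 over the list), with Aldoa 1.16 ± 0.14 and Eno1 1.15 ± 0.15. Among BMP and TGF-beta signalling genes, lower by camera (adjusted p = 0.00324, 0.036 with estimated correlation), 1 rose and 6 fell of 18 (1 and 7 over the list, 2 and 8 with the block), with Bmpr2 -0.93 ± 0.14 and Eng -0.76 ± 0.11. Within the general capillary list, lower by camera (adjusted p = 2.1e-08, 0.112 with estimated correlation), 0 rose and 6 fell of 9 (0 and 6 over the list). They were led by Kit -1.90 ± 0.25 and Plvap -1.05 ± 0.17. From the arterial list, lower by camera (adjusted p = 0.00115, 0.222 with estimated correlation), 0 rose and 4 fell of 17 (0 and 4 over the list), with Dll4 -2.72 ± 0.25 and Sema3g -2.17 ± 0.23. In the immediate early list, lower by camera (adjusted p = 0.000939, 0.208 with estimated correlation), 1 rose and 3 fell of 17 (1 and 6 over the list, 1 and 9 with the block), with Egr1 -1.47 ± 0.24 and Dusp1 -0.99 ± 0.22. Also passing were mesenchymal transition (higher, 2 and 0 of 12, 2 and 0 over the list) and oxidative phosphorylation (higher, 1 and 0 of 11, 5 and 0 over the list, 6 and 0 with the block). Their camera adjusted p was 0.00608 to 0.0341, and 0.296 to 0.381 with estimated correlation. Of the compartment gCap was 45.7% in healthy animals and 32%, 34.1% and 38.1% at weeks 1, 3 and 5. At week 1 Inflammatory ECs went from 10.4% to 20.5%, Arterial 8.27% to 4.96% and Act. Arterial 6.76% to 10.7%. This mix predicted -0.03 for Dll4, but can lower the capillary list. With the block the MHC class II and alveolar and airway marker lists also passed (camera adjusted p = 0.0428 and 0.00333, 0.71 and 0.301 without it). By edgeR, 659 of 9349 genes passed at week 1 (391 higher and 268 lower), 1514 with the block, and 588 and 773 in experiments 1 and 3 alone. That count was 414 to 439 without week 1 replicate 3 or 4. Kdr, a VEGF receptor, had -0.53 ± 0.41 (adjusted p = 0.514, and 0.0205 with the block).

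At week 3 the enzyme genes were still high in blood endothelial cells. Cyp1a1 stood at 3961 ± 1035 CPM (log2 3.47 ± 0.38, edgeR adjusted p = 5.67e-05), and Cyp1b1, Nqo1 and Igfbp3 at 4.00, 3.77 and -4.76 on the log2 scale. Ms4a8, Cnfn and the elastic fibre gene Mfap5 rose by 4.16, 5.07 and 4.24, and Tm4sf1, a tetraspanin-like protein, by 1.72 ± 0.28 (edgeR adjusted p = 0.000964). Kit fell by 1.90, Hpgd by 2.65 and Bmpr2 by 0.58, and the transcription factor Sox17 rose by 0.64. Of the hypoxia response genes, higher by camera (adjusted p = 2.6e-09, 0.012 with estimated correlation), 5 rose and 0 fell of 13 (7 and 0 over the list, 8 and 0 with the block). Leading were Eno1 1.09 ± 0.15 and Aldoa 1.05 ± 0.14. Among general capillary genes, lower by camera (adjusted p = 1.61e-06, 0.28 with estimated correlation), 0 rose and 4 fell of 9 (0 and 5 over the list), with Kit -1.90 ± 0.25 and Aplnr -1.02 ± 0.23. Within the activation and sprouting list, higher by camera (adjusted p = 0.00428, 0.132 with estimated correlation), 2 rose and 0 fell of 18 (3 and 0 over the list, 4 and 1 with the block), with Vwa1 2.74 ± 0.38 and Tm4sf1 1.72 ± 0.28. From the immediate early list, lower by camera (adjusted p = 0.00428, 0.398 with estimated correlation), 1 rose and 3 fell of 17 (1 and 3 over the list, 1 and 6 with the block). First among them were Egr1 -1.29 ± 0.23 and Dusp1 -1.05 ± 0.22. Other lists past the threshold were cell cycle (higher, 2 and 0 of 16, 4 and 0 over the list) and oxidative phosphorylation (higher, 1 and 0 of 11, 6 and 0 over the list, 4 and 0 with the block). Their camera adjusted p was 0.00307 to 0.00428, and 0.398 to 0.65 with estimated correlation. The alveolar and airway marker and leukocyte marker lists passed only with the block (camera adjusted p = 0.000146 and 0.0133, 0.208 and 0.381 without it). By edgeR, 454 of 9349 genes passed at week 3 (283 higher and 171 lower), 1311 with the block, and 531 and 605 in experiments 1 and 3 alone. That count was 281 to 290 without healthy replicate 4 or week 3 replicate 1. Nos3, the endothelial nitric oxide synthase, had 1.01 ± 0.38 (adjusted p = 0.144, and 0.000624 with the block).

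At week 5 fewer genes passed, still among them Cyp1a1, Cyp1b1 and Nqo1 (2.67, 3.58 and 3.51 above healthy). Tm4sf1 had 1.82, Igfbp3 -4.22 and Kit -1.50. Week 5 replicate 3 held 725, 107 and 114 CPM of the enzymes, against healthy maxima of 523, 159 and 110. Others that week held at least 2543, 1221 and 344. In the general capillary list, lower by camera (adjusted p = 9.58e-06, 0.243 with estimated correlation), 0 rose and 1 fell of 9 (0 and 3 over the list, 0 and 4 with the block), with Kit -1.50 ± 0.25. Of the hypoxia response genes, higher by camera (adjusted p = 0.00145, 0.243 with estimated correlation), 2 rose and 0 fell of 13 (3 and 0 over the list), with Eno1 0.62 ± 0.15 and Aldoa 0.60 ± 0.14. Passing only with the block was the alveolar and airway marker list (camera adjusted p = 0.000456, 0.312 without it). By edgeR, 96 of 9349 genes passed at week 5 (78 higher and 18 lower), 487 with the block, and 605 and 74 in experiments 1 and 3 alone. That count was 33 to 51 without week 5 replicate 1 or 2 or any healthy animal and 160 without week 5 replicate 3.

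At week 8 the enzyme genes remained high, with Cyp1a1 at 2194 ± 260.2 CPM (log2 2.62 ± 0.37, edgeR adjusted p = 0.000905), Cyp1b1 at 3.92 ± 0.63 and Nqo1 at 3.60 ± 0.67. Pooled Ecel1 CPM stood at a ratio of 134 (23.7 to 5330) to healthy, where 1 count was seen. Cnfn, Pi16 and Fst, the activin-binding follistatin, rose by 6.22, 4.15 and 3.80, and Tm4sf1 by 2.07 ± 0.28 (edgeR adjusted p = 0.000685). Falls included Igfbp3 (-4.62), Mfap2 (-2.85), Serpina1 (-2.43), Wnt5b (-2.18), the carbonic anhydrase Car2 (-2.08) and Kit (-2.04). Among general capillary genes, lower by camera (adjusted p = 6.8e-09, 0.159 with estimated correlation), 0 rose and 3 fell of 9 (0 and 6 over the list, 0 and 6 with the block). Members included Kit -2.04 ± 0.27 and Aplnr -1.21 ± 0.23. Within the hypoxia response list, higher by camera (adjusted p = 2.22e-06, 0.0639 with estimated correlation), 2 rose and 0 fell of 13 (5 and 0 over the list, 4 and 0 with the block), with Aldoa 0.78 ± 0.14 and Eno1 0.69 ± 0.15. A week 8 list that also passed was aerocyte capillary (lower, 0 and 1 of 9, 0 and 1 over the list, 0 and 3 with the block). Its camera adjusted p was 0.00734, and 0.546 with estimated correlation. Of the compartment gCap and aCap cells made up 45.7% and 6.58% in healthy animals and 33% and 3.56% at week 8, which can lower both capillary lists. Only the block brought in the alveolar and airway marker list (camera adjusted p = 7.12e-06, 0.121 without it). By edgeR, 204 of 9349 genes passed at week 8 (134 higher and 70 lower), 650 with the block, and 263 and 244 in experiments 1 and 3 alone. That count was 87 to 135 without healthy replicate 1, 2, 3 or 4 or week 8 replicate 1 or 4. Set directly against week 1, Dll4 was higher at week 8 (log2 2.65 ± 0.25, edgeR adjusted p = 1.58e-05), with Sema3g at 1.67 and Fmo2 at 2.25, and the mitotic Ube2c, Prc1 and Pttg1 were lower (-3.42, -3.46 and -3.98). Cyp1a1 had -1.23 ± 0.35 (adjusted p = 0.0673, 0.00705 with the block). In all, 245 of 9349 genes passed between them (121 higher and 124 lower), 626 with the block, and 135 and 489 in experiments 1 and 3 alone. That count was 134 to 146 without week 8 replicate 3 or 4 or week 1 replicate 3 or 4. Over the 4 weeks together 533 of 9349 genes passed in any week, 1600 with the block, and 546 and 958 in experiments 1 and 3 alone.

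**Figure D2:**
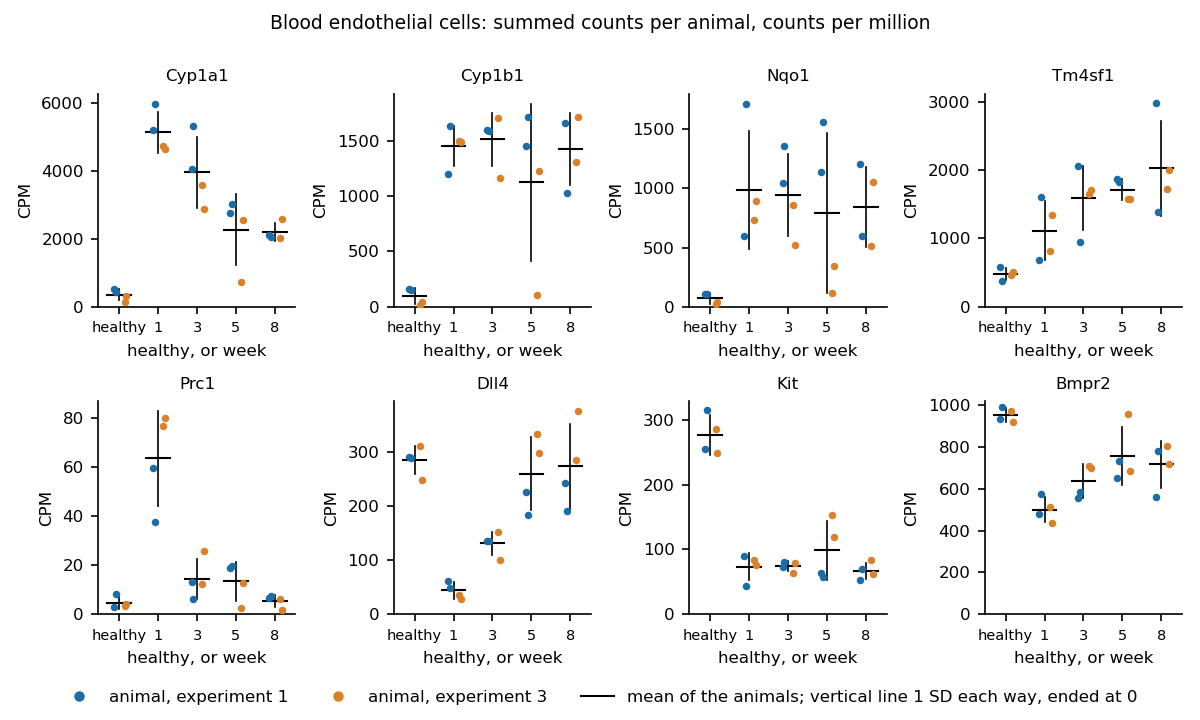
CPM (y axis) of Cyp1a1, Cyp1b1, Nqo1, Tm4sf1, Prc1, Dll4, Kit and Bmpr2 in blood endothelial cells of the 5 states (x axis). Points are animals coloured by experiment, with mean and 1 SD, ended at 0; the means of the 3 enzymes stand above healthy in every week, and the means of Prc1 and Dll4 are highest and lowest at week 1.

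In arterial endothelial cells alone, week 1 again combined mitotic rises with falls of Igfbp3 and Dll4. Healthy arterial cells held 0 to 2 pooled counts of the mitotic genes, so ratios of pooled CPM with 95% counting intervals are given. They were Prc1 84.6 (15.1 to 3355), Cdkn3 76.9 (13.7 to 3048), Ube2c 43.2 (11.8 to 358), Tpx2 34.9 (6.14 to 1389) and Birc5 18.3 (4.97 to 153), while Spc24 at least 18.8-fold and Kif22 at least 9.93-fold higher are bounds against a floor of 3 counts over the healthy group. Igfbp3 fell from 366 ± 352 to 2.45 ± 2.98 CPM (log2 -6.89 ± 0.92, edgeR adjusted p = 5.97e-05). The adenosine receptor Adora2a, Dll4, Stc1 and the leptin receptor Lepr fell by 3.65, 3.23, 2.79 and 2.40, and Bmpr2 by 0.95. From the cell cycle list, higher by camera (adjusted p = 2.98e-10, 0.135 with estimated correlation), 8 rose and 0 fell of 14 (9 and 0 over the list), with Cdk1 4.43 ± 0.67. In the arterial list, lower by camera (adjusted p = 1.37e-07, 0.135 with estimated correlation), 0 rose and 6 fell of 16 (0 and 7 over the list). They were led by Dll4 -3.23 ± 0.32 and Unc5b -1.45 ± 0.18. Of the hypoxia response genes, higher by camera (adjusted p = 0.00164, 0.135 with estimated correlation), 3 rose and 1 fell of 12 (5 and 1 over the list), with Aldoa 1.21 ± 0.16 and Eno1 1.41 ± 0.23. Other arterial-cell lists that passed at week 1 were general capillary (lower, 0 and 5 of 9, 1 and 7 over the list), extracellular matrix (higher, 3 and 0 of 14, 4 and 0 over the list), inflammatory cytokine (lower, 0 and 2 of 7, 0 and 2 over the list), immediate early (lower, 1 and 3 of 16, 1 and 8 over the list, 1 and 8 with the block), pan-endothelial marker (lower, 0 and 2 of 9, 0 and 3 over the list, 0 and 4 with the block) and oxidative phosphorylation (higher, 2 and 0 of 11, 5 and 0 over the list, 4 and 0 with the block). For these, camera gave adjusted p = 6.56e-05 to 0.0459, and 0.135 to 0.538 with estimated correlation. With the block the MHC class II, alveolar and airway marker and leukocyte marker lists also passed (camera adjusted p = 0.00211, 0.00183 and 0.00012, 0.248, 0.279 and 0.0592 without it). The Arterial type was 55% of the compartment in healthy animals and 31.4%, 50.9%, 58.4% and 62.6% at weeks 1, 3, 5 and 8, the rest being Act. Arterial, which can move the arterial list. The erythroid list passed in no comparison, though 1 and 2 of its 3 measured genes fell at weeks 1 and 3 here (camera adjusted p = 0.502 and 0.277). Without healthy replicate 2 these falls were lost, with Hbb at -0.75 and -0.68 and Hba-a2 at 0.30 (adjusted p = 0.912, 0.931 and 0.978). By edgeR, 578 of 6730 genes passed at week 1 (308 higher and 270 lower), 873 with the block, and 260 and 406 in experiments 1 and 3 alone.

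At week 3 in arterial cells Igfbp3, Cxcl1, Icam1 and 8 of 16 arterial list genes fell. Igfbp3 had -7.15 ± 0.86 (edgeR adjusted p = 2.52e-05), Adgrg6 -3.44, Lepr -3.21, C1qtnf5 -2.98 and Itm2a -2.83, while Tm4sf1 rose by 0.93. Pooled ratios were Bcat1 50.1 (8.91 to 1984) for this branched-chain aminotransferase and Trpv4 37.1 (6.59 to 1473) for the cation channel gene, against 1 healthy count each. Among arterial genes, lower by camera (adjusted p = 9.84e-08, 0.073 with estimated correlation), 0 rose and 8 fell of 16 (1 and 9 over the list, 1 and 8 with the block), with Fbln2 -2.69 ± 0.32 and Dll4 -1.95 ± 0.29. Within the inflammatory cytokine list, lower by camera (adjusted p = 0.00426, 0.073 with estimated correlation), 0 rose and 2 fell of 7 (0 and 2 over the list). Leading were Cxcl1 -4.01 ± 0.68 and Icam1 -1.59 ± 0.31. From the hypoxia response list, higher by camera (adjusted p = 0.000519, 0.073 with estimated correlation), 4 rose and 0 fell of 12 (5 and 1 over the list, 4 and 1 with the block), with Aldoa 1.07 ± 0.16 and Eno1 1.52 ± 0.23. Lists that also passed here were general capillary (lower, 0 and 4 of 9, 1 and 7 over the list, 1 and 6 with the block), activation and sprouting (higher, 3 and 1 of 17, 3 and 1 over the list), interferon response (lower, 0 and 2 of 20, 0 and 2 over the list), immediate early (lower, 1 and 2 of 16, 1 and 8 over the list, 1 and 8 with the block), pan-endothelial marker (lower, 0 and 2 of 9, 1 and 2 over the list) and oxidative phosphorylation (higher, 2 and 0 of 11, 4 and 0 over the list, 4 and 0 with the block). Their camera adjusted p was 0.000253 to 0.0456, and 0.214 to 0.425 with estimated correlation. The MHC class II and leukocyte marker lists passed only with the block (camera adjusted p = 0.00149 and 0.000411, 0.199 and 0.097 without it). By edgeR, 500 of 6730 genes passed at week 3 (275 higher and 225 lower), 816 with the block, and 384 and 266 in experiments 1 and 3 alone. Cd74 of the MHC class II pathway had -1.39 ± 0.65 (adjusted p = 0.216, 0.00127 with the block) and Sox17 0.55 ± 0.19 (0.0865 and 0.0477).

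Arterial cells at weeks 5 and 8 held less Igfbp3 (-5.80 and -6.17) and Adgrg6 (-2.23 and -2.50), with Tm4sf1 up by 1.05 and 1.29 (edgeR adjusted p = 0.0214 and 0.0051). At week 5 Serinc2 and Thbs2, a thrombospondin, stood at least 15-fold and at least 10.1-fold higher by the same floor. At week 8 pooled ratios were Cnfn 169.7 (30.3 to 6721) and Ecel1 61 (10.8 to 2428) against 1 healthy count each, and the Wnt inhibitor Wif1 fell by 2.85. In the arterial list, lower by camera (adjusted p = 0.00221, 0.267 with estimated correlation), 1 rose and 2 fell of 16 (1 and 6 over the list, 1 and 4 with the block), with Mgp -2.14 ± 0.42 and Fbln2 -1.68 ± 0.33. Of the general capillary genes, lower by camera (adjusted p = 8.92e-09, 0.0936 with estimated correlation), 0 rose and 4 fell of 9 (0 and 6 over the list). First among them were Aplnr -2.11 ± 0.49 and Gpihbp1 -2.29 ± 0.54. Week 8 arterial-cell lists that also passed were hypoxia response (higher, 1 and 0 of 12, 2 and 0 over the list, 2 and 0 with the block), immediate early (lower, 0 and 1 of 16, 0 and 2 over the list, 0 and 4 with the block) and pan-endothelial marker (lower, 0 and 1 of 9, 0 and 1 over the list, 0 and 2 with the block). Over these, camera adjusted p = 0.000129 to 0.00574, and 0.12 to 0.252 with estimated correlation. Passing only with the block were the alveolar and airway marker and leukocyte marker lists (camera adjusted p = 0.00579 and 0.00258, 0.29 and 0.213 without it). At week 5 the lists that passed were arterial (lower, 0 and 1 of 16, 1 and 6 over the list, 1 and 3 with the block), general capillary (lower, 0 and 1 of 9, 0 and 7 over the list, 0 and 5 with the block), interferon response (lower, 0 and 1 of 20, 0 and 1 over the list), inflammatory cytokine (lower, 0 and 1 of 7, 0 and 2 over the list, 0 and 2 with the block), immediate early (lower, 0 and 1 of 16, 0 and 3 over the list, 0 and 4 with the block) and pan-endothelial marker (lower, 0 and 1 of 9, 0 and 1 over the list, 0 and 2 with the block). For these, camera gave adjusted p = 8.83e-07 to 0.0117, and 0.0987 to 0.625 with estimated correlation. Only the block brought in the MHC class II and alveolar and airway marker lists (camera adjusted p = 0.00552 and 0.00395, 0.207 and 0.196 without it). By edgeR, 134 of 6730 genes passed at week 5 (87 higher and 47 lower), 319 with the block, and 291 and 26 in experiments 1 and 3 alone. That count was 61 to 89 without healthy replicate 1, 2 or 3 or week 5 replicate 1 or 2. For the last time point, 128 of 6730 genes passed at week 8 (85 higher and 43 lower), 224 with the block, and 106 and 45 in experiments 1 and 3 alone. That count was 61 to 77 without week 8 replicate 1 or healthy replicate 1, 2 or 3. Between weeks 8 and 1, Dll4, Stc1, Fmo2 and Adora2a were higher at week 8 (2.51, 2.88, 2.92 and 2.27) and Wif1 lower (-2.52). In all, 206 of 6730 genes passed between them (110 higher and 96 lower), 330 with the block, and 86 and 261 in experiments 1 and 3 alone. Taking all weeks, 498 of 6730 genes passed in any week, 837 with the block, and 302 and 488 in experiments 1 and 3 alone.

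Smooth muscle cells and pericytes at week 1 held more Des, Rgs5 and Loxl2. At this week n = 3, since 1 animal had under 20 cells, and SMCs/Myofibroblast went from a mean of 73.8% to 30.7% of the compartment. The calcium-activated chloride channel gene Ano1 rose by 3.06 ± 0.55 (edgeR adjusted p = 0.00286), Map3k7cl by 2.00 and the lysyl oxidase Loxl2 by 3.27. The lipid phosphatase Plpp3 fell by 3.59, the hedgehog-binding Hhip by 3.89 and Igf1 by 2.24 (log2), from 664 ± 276 to 127 ± 98.8 CPM. Pooled week 1 to healthy ratios were Phex 0.0182 (0.00045 to 0.107), Mal 0.025 (0.000614 to 0.15) and Tnfaip6 0.0381 (0.00447 to 0.146), and Dner at least 12.1-fold lower. Among contractile smooth muscle genes, higher by camera (adjusted p = 0.000339, 0.218 with estimated correlation), 4 rose and 0 fell of 14 (6 and 1 over the list), with Des 2.45 ± 0.33 and Myl9 1.80 ± 0.28. Within the pericyte list, higher by camera (adjusted p = 0.000339, 0.265 with estimated correlation), 3 rose and 0 fell of 14 (7 and 1 over the list, 3 and 1 with the block), with Rgs5 1.98 ± 0.44 and Cspg4 1.77 ± 0.40. From the extracellular matrix list, higher by camera (adjusted p = 0.00244, 0.115 with estimated correlation), 3 rose and 0 fell of 19 (7 and 1 over the list, 7 and 1 with the block). Members included Loxl2 3.27 ± 0.48 and Col12a1 2.10 ± 0.41. In the immediate early list, lower by camera (adjusted p = 3.48e-05, 0.115 with estimated correlation), 0 rose and 3 fell of 15 (0 and 6 over the list, 0 and 7 with the block), with Egr1 -1.94 ± 0.39 and Ier3 -1.25 ± 0.31. Endothelial-named lists that passed were venous (higher, 1 and 0 of 5, 3 and 0 over the list, 2 and 0 with the block) and activation and sprouting (higher, 4 and 0 of 12, 7 and 0 over the list). Their camera adjusted p was 4e-05 to 0.0136, and 0.115 with estimated correlation. With the block the hypoxia response list also passed (camera adjusted p = 0.0113, 0.087 without it). By edgeR, 247 of 4881 genes passed at week 1 (130 higher and 117 lower), 526 with the block, and 196 and 84 in experiments 1 and 3 alone. That count was 46 to 138 without week 1 replicate 1 or 3 or healthy replicate 2 or 3.

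At week 3 more genes passed here than in any other week of this compartment, while Acta2+ pericytes were a larger share of lung cells and 60.6% of the compartment. The small GTPase Rasd1 rose from 17.1 ± 16.2 to 302 ± 52.7 CPM (log2 4.10 ± 0.82, edgeR adjusted p = 0.00288), Ano1 by 4.21, Tesc by 4.07, Sbspon by 4.15, the synuclein Sncg by 2.75 and the glucose transporter Slc2a4 by 2.69. Among falls were Gfra2, a GDNF-family receptor (-3.67), Hhip (-3.56), Cntfr (-3.61), Ccn1 (-3.56) and Igf1 (-3.44 ± 0.48, edgeR adjusted p = 0.000133). Of the pericyte genes, higher by camera (adjusted p = 2.77e-06, 0.171 with estimated correlation), 5 rose and 0 fell of 14 (7 and 1 over the list), with Rgs5 2.95 ± 0.42 and Cspg4 2.30 ± 0.36. Among contractile smooth muscle genes, higher by camera (adjusted p = 0.000122, 0.171 with estimated correlation), 4 rose and 0 fell of 14 (6 and 0 over the list). They were led by Des 2.28 ± 0.31 and Myl9 1.55 ± 0.27. Within the hypoxia response list, higher by camera (adjusted p = 0.0352, 0.205 with estimated correlation), 5 rose and 0 fell of 9 (5 and 1 over the list), with Pgk1 1.14 ± 0.23 and Eno1 1.52 ± 0.34. From the activation and sprouting list, higher by camera (adjusted p = 0.000361, 0.171 with estimated correlation), 4 rose and 0 fell of 12 (6 and 1 over the list, 5 and 1 with the block), with Tm4sf1 3.12 ± 0.50 and Angpt2 1.57 ± 0.30. Week 3 mural lists that also passed were arterial (higher, 2 and 0 of 5, 2 and 0 over the list), general capillary (lower, 0 and 2 of 4, 0 and 2 over the list), venous (higher, 2 and 0 of 5, 2 and 0 over the list) and immediate early (lower, 0 and 1 of 15, 0 and 1 over the list, 0 and 5 with the block). Over these, camera adjusted p = 0.0352 to 0.0487, and 0.171 to 0.44 with estimated correlation. By edgeR, 414 of 4881 genes passed at week 3 (212 higher and 202 lower), and 395 and 165 in experiments 1 and 3 alone. That count was 246 without healthy replicate 3. Myh11, smooth muscle myosin, had 0.94 ± 0.34 (adjusted p = 0.0967, 0.00243 with the block).

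At week 5 Rgs5 stood above healthy in mural cells, and Eln and Col1a1 below. Rasd1, Ano1 and Sncg rose by 3.96, 3.86 and 3.12, and Igf1 fell by 2.35 (edgeR adjusted p = 0.00465). In the pericyte list, higher by camera (adjusted p = 2.4e-11, 0.075 with estimated correlation), 4 rose and 0 fell of 14 (9 and 0 over the list). Leading were Rgs5 2.33 ± 0.42 and Cspg4 1.85 ± 0.37. Of the extracellular matrix genes, lower by camera (adjusted p = 0.00406, 0.123 with estimated correlation), 0 rose and 2 fell of 19 (1 and 6 over the list, 0 and 6 with the block), with Eln -1.57 ± 0.34 and Col1a1 -1.52 ± 0.36. Among vasoactive genes, higher by camera (adjusted p = 0.00601, 0.123 with estimated correlation), 2 rose and 0 fell of 12 (2 and 0 over the list), with Pde3a 2.26 ± 0.54 and Ptgir 1.96 ± 0.50 (a phosphodiesterase and the prostacyclin receptor). Within the stromal marker list, lower by camera (adjusted p = 0.00376, 0.102 with estimated correlation), 0 rose and 2 fell of 9 (0 and 4 over the list, 1 and 4 with the block). First among them were Col1a1 -1.52 ± 0.36 and Lum -2.30 ± 0.56. Mural lists that also passed at week 5 were arterial (higher, 1 and 0 of 5, 2 and 0 over the list), general capillary (lower, 0 and 1 of 4, 0 and 2 over the list, 0 and 2 with the block), activation and sprouting (higher, 3 and 0 of 12, 4 and 1 over the list, 4 and 1 with the block), contractile smooth muscle (higher, 1 and 0 of 14, 1 and 0 over the list, 2 and 0 with the block) and pan-endothelial marker (higher, 1 and 0 of 4, 1 and 0 over the list, camera adjusted p = 0.0645 with the block). For these, camera gave adjusted p = 0.00406 to 0.0376, and 0.123 to 0.437 with estimated correlation. SMCs/Myofibroblast and Acta2+ pericytes were 31.9% and 49.7% of the compartment, against 73.8% and 15.8% in healthy animals, a mix that can move these lists. By edgeR, 121 of 4881 genes passed at week 5 (88 higher and 33 lower), 259 with the block, and 209 and 12 in experiments 1 and 3 alone. That count was 57 to 66 without healthy replicate 3 or week 5 replicate 2.

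At week 8 mural cells held Rasd1 at 428 ± 394 CPM (log2 4.57 ± 0.82, edgeR adjusted p = 0.00241), Tesc 4.44, Ano1 3.96, Sncg 3.70 and Map3k7cl 3.08. Plpp3 and Igf1 fell by 2.09 and 2.50, and Kdr transcripts stood at a pooled ratio of 0.0908 (0.0175 to 0.299). From the pericyte list, higher by camera (adjusted p = 1.97e-09, 0.0417 with estimated correlation), 5 rose and 0 fell of 14 (8 and 0 over the list), with Rgs5 2.81 ± 0.42 and Ebf1 2.06 ± 0.39. In the extracellular matrix list, lower by camera (adjusted p = 2.85e-05, 0.0417 with estimated correlation), 0 rose and 5 fell of 19 (0 and 10 over the list), with Loxl1 -2.35 ± 0.40 and Col1a1 -2.08 ± 0.38. Of the stromal marker genes, lower by camera (adjusted p = 0.000222, 0.0417 with estimated correlation), 0 rose and 3 fell of 9 (0 and 5 over the list, 1 and 4 with the block). Members included Col1a1 -2.08 ± 0.38 and Col3a1 -2.31 ± 0.58 (genes shared with the matrix list in part). Among vasoactive genes, higher by camera (adjusted p = 0.00174, 0.0586 with estimated correlation), 2 rose and 0 fell of 12 (4 and 0 over the list), with Pde3a 2.75 ± 0.54 and Ptgir 2.39 ± 0.51. Mural lists that also passed at week 8 were general capillary (lower, 0 and 2 of 4, 0 and 2 over the list), activation and sprouting (higher, 2 and 0 of 12, 4 and 2 over the list, 2 and 2 with the block) and immediate early (lower, 0 and 1 of 15, 0 and 1 over the list, 0 and 3 with the block). Their camera adjusted p was 0.00342 to 0.0267, and 0.0586 to 0.421 with estimated correlation. The mix can move them here too, with 21.1% SMCs/Myofibroblast and 54.2% Acta2+ pericytes. The contractile smooth muscle list passed only with the block (camera adjusted p = 0.0185, 0.065 without it). By edgeR, 189 of 4881 genes passed at week 8 (108 higher and 81 lower), 295 with the block, and 228 and 10 in experiments 1 and 3 alone. That count was 98 to 124 without healthy replicate 3 or 4 or week 8 replicate 1 or 2 and 305 without week 8 replicate 3. Against week 1 directly, Tesc, Sncg and Pcp4l1 were higher at week 8 (4.72, 3.38 and 2.28) and Loxl2 lower (-2.07 ± 0.39, edgeR adjusted p = 0.0105). In all, 45 of 4881 genes passed between them (16 higher and 29 lower), 123 with the block, and 22 and 11 in experiments 1 and 3 alone. That count was 15 to 29 without week 1 replicate 1, 3 or 4 or week 8 replicate 1, 2 or 4. Across the weeks 308 of 4881 genes passed in any week, 571 with the block, and 276 and 93 in experiments 1 and 3 alone. That count was 156 to 185 without healthy replicate 2 or 3. With at least 50 cells per animal, which leaves out 8 animals, 0, 19, 1 and 0 genes passed at weeks 1, 3, 5 and 8, 2 between weeks 8 and 1 and 3 in any week.

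**Figure D3:**
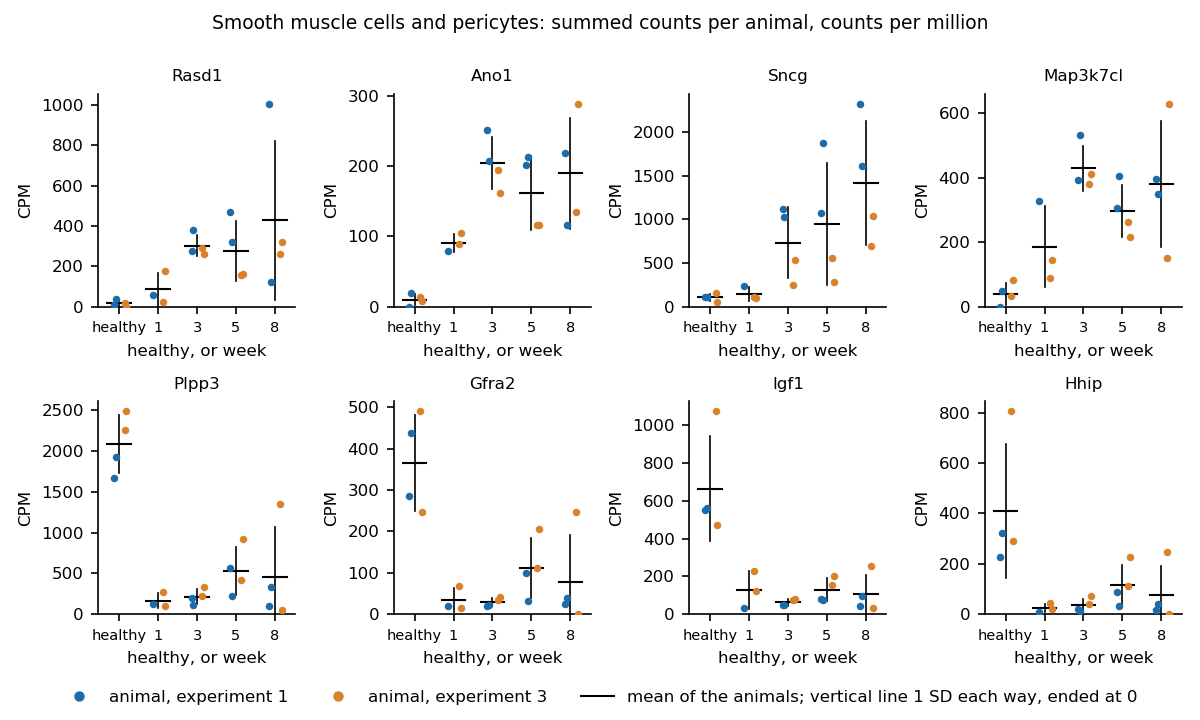
CPM (y axis) of Rasd1, Ano1, Sncg, Map3k7cl, Plpp3, Gfra2, Igf1 and Hhip in smooth muscle cells and pericytes of the 5 states (x axis). Points are animals coloured by experiment, with mean and 1 SD, ended at 0; the means of the first 4 genes stand above healthy, and those of the last 4 below, from week 3 on.

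Fibroblasts at week 1 lost the monocyte chemokine Ccl2 and gained Timp1, a metalloproteinase inhibitor. Ccl2 fell from 300.2 ± 281 to 9.64 ± 12.8 CPM (log2 -5.05 ± 1.12, edgeR adjusted p = 0.0471), and Timp1 rose from 376 ± 116 to 1783 ± 1045 CPM (log2 2.22 ± 0.45, edgeR adjusted p = 0.0305). Adamtsl2, Cnn3 and S100a11 rose by 1.93, 1.19 and 1.04, and Apoe, the actin-severing Gsn and Aldh2 fell by 1.68, 1.06 and 0.92. Within the extracellular matrix list, higher by camera (adjusted p = 0.000943, 0.82 with estimated correlation), 1 rose and 0 fell of 19 (2 and 0 over the list, 4 and 0 with the block), with Timp1 2.22 ± 0.45. Passing only with the block was the cell cycle list at week 1 (camera adjusted p = 0.0293, 0.0724 without it). By edgeR, 20 of 4076 genes passed at week 1 (7 higher and 13 lower), 118 with the block, and 145 and 31 in experiments 1 and 3 alone. That count was 1 to 13 without healthy replicate 1, 2 or 4 or week 8 replicate 1 or 2 or week 1 replicate 1, 2, 3 or 4 or week 3 replicate 1 or 2 or week 5 replicate 4 and 67 without healthy replicate 3. At weeks 3, 5 and 8 edgeR called 0, 0 and 0 genes, with 300, 274 and 300 at an unadjusted p under 0.05, and DESeq2 called 6, 1 and 0. With the block the counts were 13, 7 and 2, experiment 1 alone gave 0, 0 and 0, and experiment 3 alone 31, 12 and 29. At week 3 the count was 1 to 3 without healthy replicate 3 or week 1 replicate 2 or 3, and at week 5 2 without healthy replicate 1. Lists that passed in fibroblasts at week 3 were interferon response (higher, 0 and 0 of 9, 3 and 0 over the list), and, with 0 members past singly or over the list, contractile smooth muscle (higher) and pericyte (higher). Over these, camera adjusted p = 0.00496 to 0.0144, and 0.659 to 0.69 with estimated correlation. Only the block brought in the MHC class II and immediate early lists at week 3 (camera adjusted p = 0.0422 and 0.0394, 0.331 and 0.0522 without it). The week 5 list that passed was arterial (higher, 0 and 0 of 5, 3 and 0 over the list). Its camera adjusted p was 0.00114, and 0.0572 with estimated correlation. With the block the contractile smooth muscle list also passed at week 5 (camera adjusted p = 0.0027, 0.0815 without it). Lists that passed at week 8, where n = 3, were arterial (higher), pericyte (higher), alveolar and airway marker (higher) and pan-endothelial marker (higher), with 0 members past singly or over the list. Their camera adjusted p was 4.9e-06 to 0.0281, and 0.331 to 0.812 with estimated correlation. The contractile smooth muscle list passed only with the block at week 8 (camera adjusted p = 0.000297, 0.133 without it). The week 8 lists are markers of other cells. Against week 1, week 8 fibroblasts held more Apoe and Gsn (2.06 and 1.33) and less Timp1 and S100a11 (-2.02 and -1.50). In all, 90 of 4076 genes passed between them (38 higher and 52 lower), 224 with the block, and 203 and 31 in experiments 1 and 3 alone. That count was 11 to 49 without week 8 replicate 1, 2 or 3 or week 1 replicate 2 or 3. For the 4 weeks jointly 99 of 4076 genes passed in any week, 335 with the block, and 171 and 92 in experiments 1 and 3 alone. That count was 11 to 62 without week 1 replicate 1, 2 or 3 or week 5 replicate 1, 2, 3 or 4 or week 8 replicate 2 or 3 or healthy replicate 4.

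Macrophages and monocytes changed most at week 1, with more transcripts of the complement C1q chains and of MHC class II genes. The chemokine Ccl7 rose from 4.92 ± 3.41 to 154 ± 114 CPM (log2 4.95 ± 0.83, edgeR adjusted p = 0.000822) and Ms4a7 from 28.2 ± 8.78 to 488 ± 140.1 (log2 4.10 ± 0.35, edgeR adjusted p = 1.52e-06). C1qa, C1qb and C1qc, the chains of complement C1q, rose by 2.74, 2.72 and 2.51, the chemokines Cxcl10 and Pf4 by 2.14 and 2.02, and Mfge8 by 2.21. Eno3, G0s2, Spn (the sialoglycoprotein CD43), S1pr5 and Srgn fell by 2.21, 1.93, 1.81, 1.85 and 1.62. In healthy animals and at weeks 1 and 3, Int. Mac cells were 5.52%, 24.3% and 11.8% and Cd16+ Mono cells 47%, 18.8% and 30.3% of the compartment, which can move these genes and lists. From the MHC class II list, higher by camera (adjusted p = 8.1e-21, 0.00162 with estimated correlation), 6 rose and 0 fell of 7 (7 and 0 over the list). They were led by RT1-Ba 1.51 ± 0.14 and RT1-Da 1.62 ± 0.15 (similar RT1 genes can share reads). In the alternative macrophage list, higher by camera (adjusted p = 0.000551, 0.387 with estimated correlation), 5 rose and 0 fell of 14 (7 and 0 over the list, 9 and 0 with the block), with Fabp5 1.77 ± 0.36 and Gpnmb 1.03 ± 0.25. Of the monocyte genes, lower by camera (adjusted p = 0.000305, 0.387 with estimated correlation), 0 rose and 4 fell of 10 (0 and 4 over the list, 0 and 7 with the block), with Treml4 -1.56 ± 0.28 and Plac8 -1.49 ± 0.31. Among cell cycle genes, higher by camera (adjusted p = 3.64e-05, 0.609 with estimated correlation), 2 rose and 0 fell of 18 (11 and 0 over the list, 10 and 0 with the block). Leading were Birc5 1.37 ± 0.28 and Mcm2 1.07 ± 0.30. The interferon response list did not pass (camera adjusted p = 0.933), and its median of 0.10 and mean of 0.34 lay above 0 while camera ranked it lower. By edgeR, 1129 of 9950 genes passed at week 1 (489 higher and 640 lower), 2558 with the block, and 756 and 1186 in experiments 1 and 3 alone. That count was 605 to 725 without healthy replicate 4 or week 1 replicate 4.

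At week 3 Ms4a7, Jaml, C1qa and C1qb stood 2.46, 2.26, 1.74 and 1.75 above healthy in these cells (C1qa edgeR adjusted p = 0.0425). Within the MHC class II list, higher by camera (adjusted p = 3.19e-14, 0.0103 with estimated correlation), 4 rose and 0 fell of 7 (6 and 0 over the list), with RT1-Db1 1.06 ± 0.17 and RT1-Ba 0.83 ± 0.14. From the immediate early list, higher by camera (adjusted p = 0.0038, 0.449 with estimated correlation), 1 rose and 0 fell of 17 (3 and 1 over the list, 4 and 1 with the block), with Dusp1 0.34 ± 0.08. By edgeR, 57 of 9950 genes passed at week 3 (41 higher and 16 lower), 554 with the block, and 145 and 32 in experiments 1 and 3 alone. That count was 4 to 36 without healthy replicate 1 or 4 or week 3 replicate 2 or 3 or week 8 replicate 3 or week 5 replicate 2 and 189 without week 3 replicate 4. At weeks 5 and 8 edgeR called 0 and 0 genes, with 279 and 516 at an unadjusted p under 0.05, DESeq2 called 0 and 5, and the block 0 and 0. Experiment 1 alone gave 8 and 15 and experiment 3 alone 0 and 0, and leaving out week 8 replicate 4 gave 1 gene at week 8. At week 5 the list that passed was interferon response (lower), with 0 members past singly or over the list. Its camera adjusted p was 4.86e-05, and 0.947 with estimated correlation. Passing only with the block was the monocyte list at week 5 (camera adjusted p = 0.0481, 0.437 without it). Only the block brought in the monocyte list at week 8 (camera adjusted p = 0.00274, 0.196 without it). Directly against week 1, week 8 cells held less Ccl7, Ms4a7 and C1qa (-4.54, -2.55 and -2.14) and more Eno3, G0s2 and Spn (1.58, 1.45 and 1.44). In all, 421 of 9950 genes passed between them (240 higher and 181 lower), 1360 with the block, and 165 and 504 in experiments 1 and 3 alone. That count was 157 to 275 without week 1 replicate 3 or 4 or week 8 replicate 3 or 4. Jointly over the weeks, 579 of 9950 genes passed in any week, 1918 with the block, and 297 and 450 in experiments 1 and 3 alone. That count was 239 to 356 without week 1 replicate 2, 3 or 4.

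Some lists passed by camera with 0 members past singly, with the members past over the list given here. In blood endothelial cells these were at week 3 interferon response (lower, 0 and 0 of 23), at week 5 interferon response (lower, 0 and 0 of 23), cell cycle (higher, 0 and 0 of 16), extracellular matrix (higher, 3 and 0 of 19), immediate early (lower, 0 and 0 of 17), pan-endothelial marker (lower, 0 and 0 of 9) and oxidative phosphorylation (higher, 0 and 0 of 11), and at week 8 immediate early (lower, 0 and 0 of 17), pan-endothelial marker (lower, 0 and 1 of 9) and oxidative phosphorylation (higher, 4 and 0 of 11). Over them camera adjusted p = 0.000847 to 0.0191, and 0.243 to 0.724 with estimated correlation. In arterial cells they were at week 3 cell cycle (higher, 0 and 0 of 14, camera adjusted p = 0.0562 with the block) and alveolar and airway marker (lower, 0 and 0 of 9), at week 5 leukocyte marker (lower, 0 and 0 of 9) and oxidative phosphorylation (higher, 0 and 0 of 11), and at week 8 oxidative phosphorylation (higher, 1 and 0 of 11). Over them camera adjusted p = 0.0191 to 0.0477, and 0.252 to 0.737 with estimated correlation. In mural cells those were at week 5 venous (higher, 0 and 0 of 5) and immediate early (lower, 0 and 1 of 15). Over them camera adjusted p = 0.000557 to 0.033, and 0.123 to 0.133 with estimated correlation. In macrophages and monocytes such lists were at week 3 interferon response (lower, 0 and 1 of 24), cell cycle (lower, 0 and 0 of 18), inflammatory cytokine (higher, 1 and 0 of 13), alternative macrophage (higher, 2 and 0 of 14) and monocyte (lower, 0 and 0 of 10). Over them camera adjusted p = 5.23e-05 to 0.0103, and 0.449 to 0.742 with estimated correlation.

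Genes chosen before the files were seen had these log2 fold changes at weeks 1, 3, 5 and 8. In blood endothelial cells they were Tm4sf1 1.21, 1.72, 1.82 and 2.07, Bmpr2 -0.93, -0.58, -0.34 and -0.41, Sox17 0.14, 0.64, 0.37 and 0.41, Cd74 -0.45, -0.48, -0.44 and -0.32, Kdr -0.53, -0.42, -0.11 and -0.27, Edn1 -0.05, 0.44, 0.17 and 0.58 and Nos3 0.74, 1.01, 1.15 and 1.12. Tm4sf1 passed at each week, Bmpr2 at weeks 1 and 3, Sox17 at week 3, and Cd74, Kdr, Edn1 and Nos3 at none (smallest edgeR adjusted p = 0.144). The block brought in Nos3 at each week, Kdr at week 1 and Bmpr2 at week 8 (adjusted p = 0.000624 to 0.0444). In arterial cells they were Tm4sf1 0.70, 0.93, 1.05 and 1.29, Bmpr2 -0.95, -0.72, -0.54 and -0.43, Sox17 0.23, 0.55, 0.10 and 0.12, Cd74 -1.32, -1.39, -1.20 and -0.80, Kdr -0.43, 0.15, 0.17 and 0.26, Edn1 -0.07, 0.02, -0.15 and 0.51 and Nos3 0.17, 0.42, 0.70 and 0.64. Tm4sf1 passed at weeks 3, 5 and 8, Bmpr2 at weeks 1 and 3 and the rest at none (smallest 0.0865), with Tm4sf1 at week 1, Cd74 at weeks 1, 3 and 5 and Sox17 at week 3 added by the block (0.00127 to 0.0477). In mural cells Acta2 0.66, 0.50, 0.03 and 0.12, Myh11 0.20, 0.94, 0.69 and 0.73, Postn 0.28, 0.15, 0.52 and 0.54 and Notch3 0.50, 1.38, 1.58 and 1.34 passed at none (smallest 0.0681), and with the block Myh11 passed at weeks 3, 5 and 8 and Notch3 at week 5 (0.00243 to 0.0442).

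**Figure D4:**
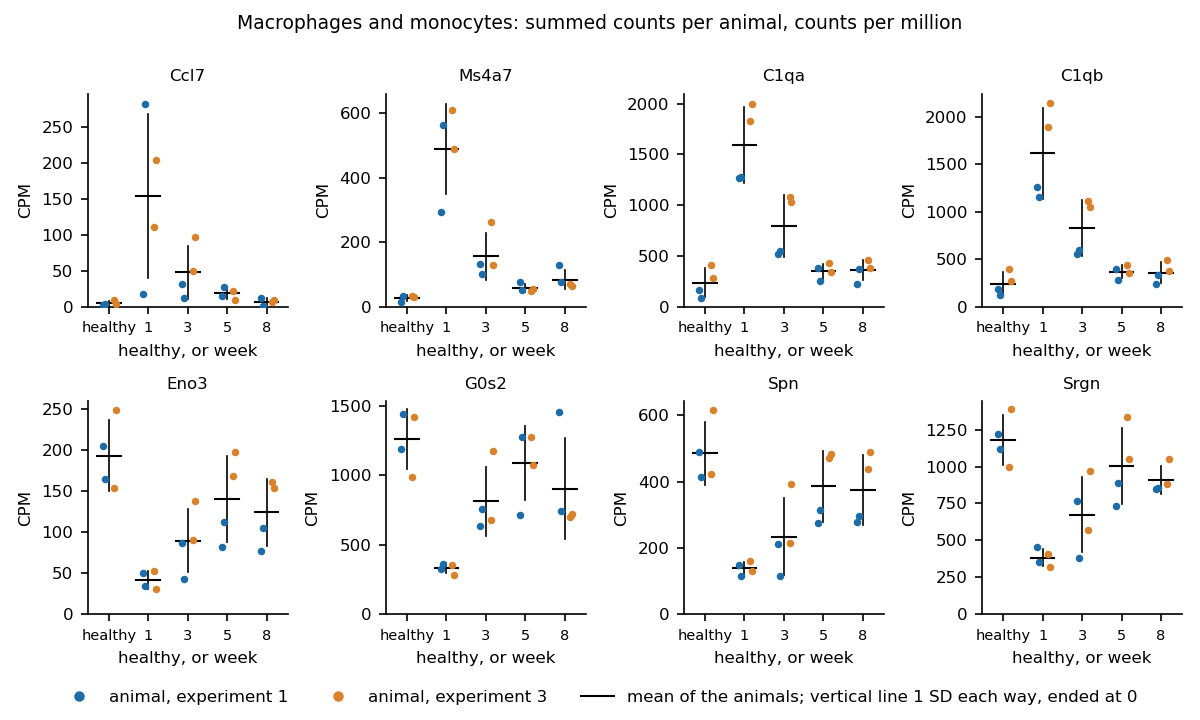
CPM (y axis) of Ccl7, Ms4a7, C1qa, C1qb, Eno3, G0s2, Spn and Srgn in macrophages and monocytes of the 5 states (x axis). Points are animals coloured by experiment, with mean and 1 SD, ended at 0; by their means the first 4 genes are highest at week 1 and the last 4 lowest.

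**Figure D5:**
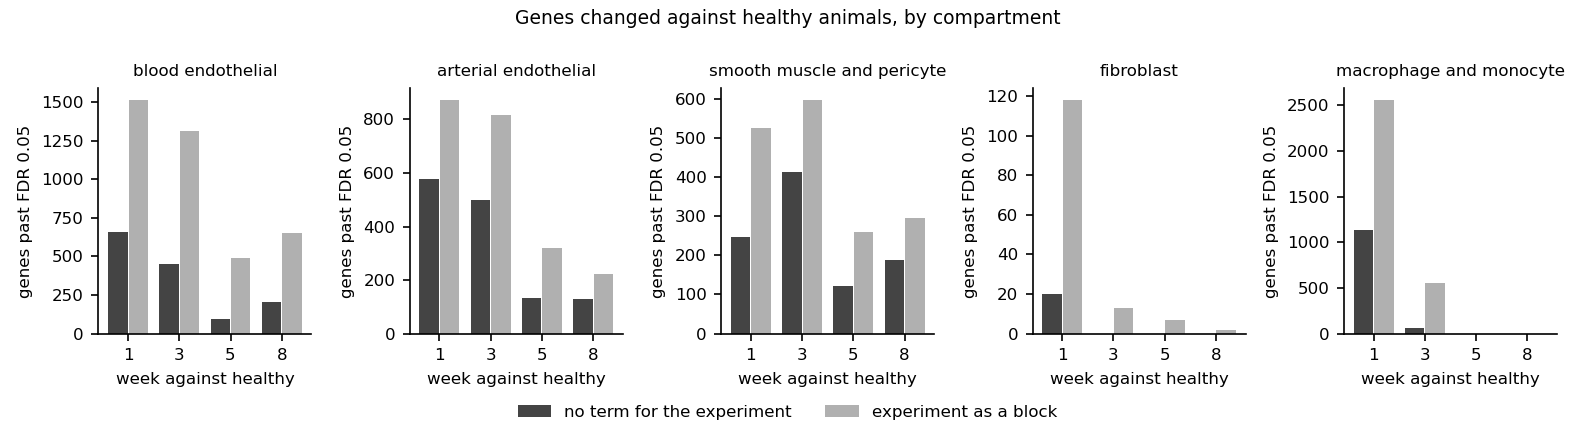
Number of genes past an edgeR adjusted p of 0.05 (y axis) per compartment and week against healthy (x axis). Dark bars are the fit with no term for experiment and light bars the fit with that term; the tallest dark bar is the 1129 genes of macrophages and monocytes at week 1.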

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

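The splits of the animals, all tests of patterns other than the NRF2, receptor target and fibroblast mix tests, the fits of single cell types, and the share comparison of week 8 with week 1 were chosen after the results were seen. Week 8 and week 1 differed directly in 245 genes in blood endothelial cells, 206 in arterial cells, 45 in mural cells, 90 in fibroblasts and 421 in macrophages and monocytes, and in the shares of 7 cell types.

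Single animals stood apart in 18 of 211 gene and state groups tested and 1 of 30 share groups. The value given is the animal's log2 CPM against the mean of the other 3, and the gap is that to the nearest other animal as a share of the range. In blood endothelial cells these were Ecel1 in healthy replicate 4 (1.53 against 0.61, gap 1), Fst in healthy replicate 2 (2.10 against 3.62, gap 0.845) and Serpina1 in week 8 replicate 1 (2.56 against 4.94, gap 0.96). In arterial cells Thbs2 in week 5 replicate 3 stood at 3.81 against 6.24 (gap 0.841). Another 8 genes were counted in 1 healthy animal alone: Cdkn3, Bcat1, Cks2 and Ube2c (replicate 1), Cnfn and Prc1 (2), Trpv4 (3) and Ecel1 (4). This, as for Ecel1 above, forces a gap of 1, so the 18 cannot be set against the 10.55 of chance. In fibroblasts they were S100a11 in week 1 replicate 4 (10.10 against 10.21, gap 0.84) and Ppp1r14b in healthy replicate 4 (6.83 against 7.55, gap 0.867), and in macrophages and monocytes Ms4a7 in healthy replicate 1 (3.96 against 5.04, gap 0.923), Jaml in week 1 replicate 2 (5.94 against 6.56, gap 0.834), S1pr5 in week 1 replicate 3 (4.87 against 4.41, gap 0.875) and Mal in healthy replicate 4 (9.82 against 9.21, gap 0.884). The last was the Brush cell share of week 8 replicate 2 (0.0701% against a mean of 0.334%, gap 0.83).

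Barcodes outside the authors' annotation were not empty. Their median UMI count was 2117, 2627.5, 3656.5 and 3894 in libraries A1, B1, A2 and B2, against 2136, 2606, 2994 and 3039 in annotated cells.

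Other splits of the animals into groups of the same sizes were counted for each gene count, 35 per comparison of 2 states and 100 drawn for any week. Chance can be excluded where 1 split, the real one, was as large. That held for blood endothelial cells in any week (highest other 14), at weeks 1 (262) and 8 (1) and between weeks 8 and 1 (0). It held for arterial cells in each comparison (highest others, any week first and week 8 against week 1 last, 32, 9, 1, 8, 1 and 1), and for mural cells at weeks 1, 3, 5 and 8 and between weeks 8 and 1 (78, 1, 36, 1 and 5). For mural cells in any week 2 of 100 splits were as large, the other with 331 genes against 308, a share still under 0.05. In fibroblasts it held in any week (38) and between weeks 8 and 1 (44), and in macrophages and monocytes in any week (14), at weeks 1 and 3 (0 and 0) and between weeks 8 and 1 (0). The share was over 0.05 for blood endothelial cells at week 3 (2 of 35 splits, the other with 589 genes against 454) and week 5 (2 of 35, 451 against 96) and fibroblasts at week 1 (2 of 35, 47 against 20). In each the larger count came from the split that follows the experiment, with 1311, 487 and 118 genes in the blocked fits of the real groups. In the 18 even splits, too few for a share under 0.05, the highest others there were 0, 0 and 4 genes. A count of 0 is matched by all 35 splits whatever the data, so these decide nothing there. Other splits gave up to 45, 141 and 1 genes in fibroblasts at weeks 3, 5 and 8 and up to 1247 and 1 in macrophages and monocytes at weeks 5 and 8. The 45, 141 and 1247 came from the split by experiment, which points to a structure of the samples by experiment. The blocked fits of the real groups gave 13, 7 and 0 genes there. Shares gave 2 of 35 splits as large at weeks 1 and 3, again by experiment (11 types against 5, and 12 against 4; 14 and 17 with the block; highest others 0 and 0 in the 18 even splits), and 1 of 35 at weeks 5 and 8 (highest others 0 and 2). The numbers of lists past the threshold did not meet the rule. At weeks 1, 3, 5 and 8, 16, 13, 14, 19 of 35 splits were as large in blood endothelial cells, 4, 3, 6, 8 in arterial cells, 14, 5, 3, 9 in mural cells, 29, 21, 23, 21 in fibroblasts and 25, 13, 30, 35 in macrophages and monocytes, whose 35 at week 8 goes with a real number of 0 and decides nothing. Real numbers ran from 0 to 11 and the highest other splits from 10 to 17 lists. In the 18 even splits no other was as large in arterial cells (9, 11, 8 and 6 lists against highest others of 7, 8, 5 and 4), in mural cells at weeks 3 and 5 (8 against 7, 11 against 6) or in macrophages and monocytes at week 3 (7 against 4).

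Cyp1a1, Cyp1b1, Nqo1, Tiparp and Ahrr were higher in blood endothelial cells at week 8. A change in the mix of endothelial types is argued against by gCap cells alone (median log2 fold change 3.09). RNA from other cells is argued against for Cyp1a1, at most 358 CPM outside the blood endothelium against 2524 in gCap. Cyp1b1 stays open (897 in SMCs/Myofibroblast, gCap 1138, gCap ERG 752). So do Nqo1 (319 in AT2-a, gCap 491), Tiparp (194 in Megakaroycyte, gCap 168) and Ahrr (60.1 in Pdzd2+ Pericyte, gCap 57.1). Activity of the aryl hydrocarbon receptor stays open: 3 of 10 other target genes could be tested (median 0.96), and 1, Nfe2l2, passed (1.08, edgeR adjusted p = 0.00179). An NRF2 oxidative stress response stays open too: 6 of 9 genes were tested (median 0.606, upper quartile 1.10) and 0 passed. With the block 2 did, Me1 (2.97, adjusted p = 0.0121) and Gclc (1.19, 0.0318). Disease stage and the way the disease was induced cannot be separated in these groups.

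The immediate early list was lower by camera in blood endothelial and mural cells at weeks 1, 3, 5 and 8. Adjusted p was 0.000847 to 0.0075 and 3.48e-05 to 0.0437 (0.208 to 0.541 and 0.115 to 0.44 with an estimated correlation). In the former 0 members passed at weeks 5 and 8. A change in the mix of types is argued against by gCap cells alone, where the list median at week 1 was -0.64, while Venous cells had -0.19 with an upper quartile of 0.124 and 0 fallen. Macrophages and monocytes cannot decide on handling that raised these genes in all healthy lung cells, as their types differed. Their summed median was 0.37 at week 3 (quartiles 0.21 and 0.48). Int. Mac cells had -0.89 at week 1, with 8 of 15 fallen. Handling or a difference that belongs to the disease may remain, untested.

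A changing mix of types within a compartment could move its summed genes. The ratio of the change expected from the mix to that observed was computed for named genes, not lists. Its median was 0.0749 in blood endothelial, 0.0482 in arterial, 0.41 in mural and 0.0982 in fibroblast genes. Naming by large changes lowers it, and 0 healthy counts force 0. It argues against the mix as the whole cause for blood endothelial and fibroblast genes and arterial falls. Mural genes stay open (4 of 24 over 0.5, with 28 healthy Acta2+ pericytes). So do macrophage and monocyte genes (median 0.668, quartiles 0.445 and 0.741, 15 of 24 over 0.5).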

How the results depend on the processing

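The fits with experiment 1 or experiment 3 alone, and the block in the list tests, were added after the data were examined; the other settings were fixed before. Gene counts that moved by over 1.5 times are given per comparison (wk, a week against healthy, 8 against 1, or any), and the others stayed within that. With DESeq2 size factors in edgeR all 30 counts stayed within 1.5 times. The pool replicate block gave blood endothelial 1600 (any), 1514 (wk 1), 1311 (wk 3), 487 (wk 5), 650 (wk 8), 626 (8 against 1), arterial 837 (any), 873 (wk 1), 816 (wk 3), 319 (wk 5), 224 (wk 8), 330 (8 against 1), mural 571 (any), 526 (wk 1), 259 (wk 5), 295 (wk 8), 123 (8 against 1), fibroblast 335 (any), 118 (wk 1), 13 (wk 3), 7 (wk 5), 2 (wk 8), 224 (8 against 1) and macrophage and monocyte 1918 (any), 2558 (wk 1), 554 (wk 3), 1360 (8 against 1), moving 27 of 30, and beyond the calls given with it in the report, and those of 2 NRF2 genes, it changed no other call stated there. DESeq2 gave blood endothelial 847 (any), 195 (wk 5), 309 (wk 8), arterial 216 (wk 5), mural 75 (8 against 1), fibroblast 197 (any), 62 (wk 1), 6 (wk 3), 1 (wk 5) and macrophage and monocyte 1063 (any), 189 (wk 3), 5 (wk 8), 638 (8 against 1). Cells thinned to 1000 UMIs gave blood endothelial 232 (any), 233 (wk 1), 133 (wk 3), 20 (wk 5), 66 (wk 8), 105 (8 against 1), arterial 165 (any), 193 (wk 1), 93 (wk 3), 38 (wk 5), 22 (wk 8), 93 (8 against 1), mural 88 (any), 40 (wk 1), 132 (wk 3), 39 (wk 5), 74 (wk 8), 7 (8 against 1), fibroblast 13 (any), 1 (wk 3), 14 (8 against 1) and macrophage and monocyte 301 (any), 529 (wk 1), 217 (8 against 1), with fewer cells and shallower counts by construction. Without a filter on low counts the numbers were arterial 820 (any), 234 (wk 5), 204 (wk 8), 326 (8 against 1), mural 775 (any), 479 (wk 1), 319 (wk 5), 381 (wk 8), 231 (8 against 1), fibroblast 562 (any), 183 (wk 1), 123 (wk 3), 135 (wk 5), 136 (wk 8), 334 (8 against 1) and macrophage and monocyte 35 (wk 3). A minimum of 50 cells, which leaves out animals, gave mural 3 (any), 0 (wk 1), 19 (wk 3), 1 (wk 5), 0 (wk 8), 2 (8 against 1) and fibroblast 44 (wk 1). Fitting 2 states only gave blood endothelial 45 (wk 5), 134 (wk 8), 153 (8 against 1), arterial 136 (8 against 1), mural 20 (8 against 1), fibroblast 1 (wk 1), 49 (8 against 1) and macrophage and monocyte 9 (wk 3). Experiment 1 alone gave blood endothelial 605 (wk 5), 135 (8 against 1), arterial 302 (any), 260 (wk 1), 291 (wk 5), 86 (8 against 1), mural 209 (wk 5), 22 (8 against 1), fibroblast 171 (any), 145 (wk 1), 203 (8 against 1) and macrophage and monocyte 297 (any), 145 (wk 3), 8 (wk 5), 15 (wk 8), 165 (8 against 1), and experiment 3 alone blood endothelial 958 (any), 489 (8 against 1), arterial 266 (wk 3), 26 (wk 5), 45 (wk 8), mural 93 (any), 84 (wk 1), 165 (wk 3), 12 (wk 5), 10 (wk 8), 11 (8 against 1), fibroblast 31 (wk 1), 31 (wk 3), 12 (wk 5), 29 (wk 8), 31 (8 against 1) and macrophage and monocyte 32 (wk 3), with 2 animals per state. Leaving out 1 animal at a time gave, in the order any week, weeks 1, 3, 5 and 8, and 8 against 1, 410–558, 414–717, 281–492, 33–160, 87–218 and 134–254 (blood endothelial), 383–514, 387–627, 345–526, 61–192, 61–150 and 140–230 (arterial), 156–369, 46–292, 246–438, 57–145, 98–305 and 15–63 (mural), 11–130, 1–67, 0–3, 0–2, 0–0 and 11–128 (fibroblast) and 239–666, 605–1217, 4–189, 0–0, 0–1 and 157–463 (macrophage and monocyte).

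For shares, 15 calls became 51 with the replicate block, 0 by the exact permutation test, whose smallest p cannot pass, 33 in experiment 1 alone and 7–15 with 1 animal left out. TMM scaling, lineage denominators, limma and experiment 3 alone gave 12, 13, 10 and 17. For lists, 116 calls became 9 with an estimated correlation and 71 with fry, whose question differs, while leaving out 1 animal gave 106–131. The 9 were hypoxia response at weeks 1 and 3 and cell cycle and BMP and TGF-beta signalling at week 1 in blood endothelial cells, MHC class II at weeks 1 and 3 in macrophages and monocytes, and pericyte, extracellular matrix and stromal lists at week 8 in mural cells. The block ended 2 list calls, cell cycle in arterial cells at week 3 (camera adjusted p = 0.0562) and pan-endothelial markers in mural cells at week 5 (0.0645).

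Of the single genes, calls were lost in 6 of 468 with DESeq2, 2 of 478 with its size factors, 130 of 379 when thinned, 158 of 477 with the cell minimum, 20 of 478 without a filter and 47 of 442 with 2 states. Experiments 1 and 3 alone lost 110 of 473 and 160 of 475, and leaving out 1 animal 978 of 9374. The sign of the log2 fold change turned for Cd74 in blood endothelial cells at week 3 from -0.48 to 0.057 without healthy replicate 2 (-0.94 to 0.057 over the animals left out), Kdr in arterial cells at week 1 from -0.43 to 0.22 when thinned, Sox17 in arterial cells at week 3 from 0.55 to -0.080 when thinned, Sdhb in arterial cells at week 3 from 0.63 to -0.072 when thinned, Hba-a2 in arterial cells at week 3 from -4.54 to 0.30 without healthy replicate 2 (-5.16 to 0.30 over the animals left out), Edn1 in arterial cells at week 8 from 0.51 to -0.54 in experiment 1 alone, and Postn in mural cells at week 8 from 0.54 to -0.066 without week 8 replicate 4 (-0.066 to 0.83 over the animals left out) and -0.50 in experiment 1 alone. Beyond what each setting's construction shows, the cause was not tested. In simulated data 21% and 29% of 2-fold changes, all in genes with a mean of at least 50 CPM, were recovered in mural cells and fibroblasts, against 77% and 87% in blood endothelial cells and in macrophages and monocytes, and this does not part a limit by depth from one by the number of cells or animals.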
